A study of Homo sapiens with 9 samples.

How the data were processed

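Small RNA libraries from the human colorectal carcinoma line HCT116 and its knockout clones were sequenced in 2 sets. Per the labels, 10 µg of total RNA was run on a 15% gel and RNA of 17 to 30 nt was cut out and sequenced on a MiSeq. Set 1 held 2 parental libraries and 2 libraries of DROSHA knockout clone 40. With a single DROSHA clone, the p-values of that knockout do not cover differences between clones. Set 2 held 1 parental library, XPO5 knockout clones 19 and 19-1, and DICER knockout clones 43 and 45. Groups came from the sample titles. The labels do not say how clones 19 and 19-1 relate. They were treated as replicates, and if one derives from the other, the XPO5 SDs and p-values describe a single clone. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

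The deposited values are raw read counts per mature miRNA, with no normalization. The submitters' processing notes name Bowtie2 and the GRCh38 build. The Bowtie2 version and the handling of reads that match several copies of a miRNA are not given in the sources used here. Each library lists only the miRNAs with reads, so an unlisted miRNA was given a count of 0. The 9 libraries together name 1314 miRNAs. The count of reads outside miRNAs is unknown, so total miRNA counts served as the depth, and all levels are shares of miRNA counts in CPM, the deposited count divided by the library total and scaled. A fall in all miRNAs together would not show on this scale.

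Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the miRNA total as library size and no further normalization factor. The SE of a log2 change was derived from this test, as the absolute log2 change divided by the square root of the F statistic. miRNAs with at least 20 counts summed over the fitted libraries were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. Set 1 was fitted with its 4 libraries and set 2 with its 5 libraries in 3 groups, where the lone parental library was assumed to vary like the clones. Differences between effects were tested in a model of all 9 libraries. Lists of miRNAs were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, and with fry. Changes of the 5p and 3p arms of a hairpin were compared over hairpins with both arms tested by 100000 random sign flips of the mean difference, two-sided. Hairpins are not independent replicates. Shares of single libraries have exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, because reads carry no molecular identifiers. A fold against a group with no counts is a lower bound set by 3 counts over the group. Fitted log2 changes of such miRNAs are not bounds, so medians are also given with these miRNAs at their bound, taken as 0 where the floor exceeds the other group.

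Before the data were examined, the comparisons, the tests, the lists and the rule for naming miRNAs were fixed. For each comparison the text names the 8 miRNAs highest in the reference, the 8 highest in the knockout, the 6 largest rises and 6 largest falls past the threshold with all knockout libraries on the same side of all reference libraries, and the tested members of the lists of DROSHA-independent precursors, mirtrons and DICER-independent miRNAs. Other lists are described as groups with up to 4 examples, those highest in the reference. Alternatives planned then were TMM factors, DESeq2 size factors, scaling to the miR-320 family and miR-484, the DESeq2 1.42.0 Wald test, no filter, at least 200 counts, all 9 libraries, thinned libraries, each replicate left out, a replicate block, and pooled parental libraries. Summing copies, totals without miR-21-5p, leaving out miRNAs unstable between replicates, and 5 restrictions of the arm comparison were added after seeing the data. Summing copies joined all names with the same number and arm, such as miR-10a-5p and miR-10b-5p, so it also joined distinct miRNAs. For the arms in the DICER knockout, 2 weighing tests were reworded after their values were known. The one of a miR-21-5p share effect first left out the miR-21 hairpin, which cannot show such an effect, and now uses hairpins with counts on both arms in both groups. The one against XPO5 clones was first read as support and is now read as undecided. For detection, each library was thinned to 89812 counts in 100 draws.

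The test was run on simulated counts with 200 changed miRNAs and a dispersion of 0.2. For the DROSHA design with 431 miRNAs tested, it called 40% of those changed by 2 log2 units and 95% of those changed by 4. There 16.1% of the calls were miRNAs that had not been changed. Abundant changed miRNAs had moved the library total, so that the share of the others fell by 1.303 log2 units. A second simulation, added after seeing this, drew the changed miRNAs outside the 30 most abundant, and it called 48.5% and 88% at those sizes, with 2.2% of its calls unchanged miRNAs and a shift of -0.448. The median log2 change in the DROSHA data was -3.47, further than either shift, so these rates may not hold for its calls. For the XPO5 design with 444 miRNAs tested, the first simulation called 37.8% and 96.6% at those sizes, and 3.2% of the calls were unchanged, and the second called 34.1% and 96.6%, with 0.8% unchanged. The permutation test by sign flips gave p = 0.743 for 101 simulated hairpins with no difference and p = 1e-05, the smallest it can give, for a difference of 2.

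Hairpin positions are those of GENCODE release 29 on GRCh38, reached through gene symbols and synonyms. A first match on synonyms with a species prefix placed 53.2% of names, too few for use, and was widened after its result was seen. The final match placed 512 of 513 tested names (99.8%). Figures were drawn with matplotlib 3.10.9.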

Results

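The study measured mature miRNAs in HCT116 cells that lack DROSHA, Exportin 5 (XPO5) or DICER. DROSHA cuts primary transcripts in the nucleus, XPO5 carries the resulting hairpins to the cytoplasm, and DICER cuts off the loop. Its title names a re-evaluation of the part each protein plays. The parental libraries held 2245875 and 1730416 miRNA counts in set 1 and 1771763 in set 2. The DROSHA knockout libraries held 96899 and 89812 counts, the XPO5 knockout clones 671760 and 1044144, and the DICER knockout clones 278282 and 394769. The mRNAs of the 3 targeted genes are not measured by these libraries, so the knockouts cannot be checked on them here.

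Without DROSHA, the miR-320 family and miR-484, whose precursors are transcribed directly with a cap, and the mirtrons, which are released by splicing, rose as a share of miRNA counts. The DROSHA-independent precursors rose from 0.4428% ± 0.0511 of miRNA counts in the parental libraries to 52.23% ± 0.94 (SD, n = 2 each), and the mirtrons from 0.09299% ± 0.026 to 14.07% ± 3.03. Without the most abundant miRNA of each library, which was miR-320a in the knockout, the shares went from 0.5162% ± 0.0648 to 22.35% ± 4.29 and from 0.1085% ± 0.0314 to 23.08% ± 6.63. miR-320a rose 129.9-fold, from 2952 ± 310.3 to 383570 ± 46055 CPM (log2 change 7.02, SE 0.30, adjusted p = 0.00187). Canonical miRNAs fell. miR-21-5p, the most abundant parental miRNA, was 10.7-fold lower (log2 change -3.42, SE 0.41, adjusted p = 0.00398). Of 487 miRNAs tested with edgeR, 111 were higher and 236 lower after Benjamini-Hochberg adjustment. The median log2 change was -3.47, or -0.85 with miRNAs without a count in one group at their bound.

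All 8 tested mirtrons, of 17 named in the libraries, rose, and 8 did so adjusted over the list alone. Of these, miR-1226-3p, miR-1228-3p, miR-1229-3p, miR-1234-3p and miR-877-3p had 10, 1, 12, 7 and 9 parental counts. They reached the counts needed for testing only through the knockout, so the 8 of 8 is partly built in. The rises of miR-877-5p, miR-1224-5p and miR-1226-5p, with 3416, 120 and 22 parental counts, do not share this limit. miR-877-5p, from an intron of ABCF1 on chromosome 6 (30584332 to 30584417, GRCh38), rose 151.3-fold to 133395 CPM. miR-1224-5p rose 97.2-fold, miR-1226-3p 451.2-fold, miR-1226-5p 114.9-fold, miR-1229-3p 506.2-fold, miR-1234-3p 83.2-fold and miR-877-3p 131.3-fold. miR-1228-3p also rose, from 1 count in the parental libraries to 26. Of the 5 DROSHA-independent miRNAs, 4 rose, and 4 did so adjusted over the list alone. They were miR-320a (chromosome 8, 22244962 to 22245043, intergenic), miR-320c (41.8-fold), miR-320d (66.8-fold) and miR-484 (120.2-fold; chromosome 16, 15643294 to 15643372, at a transcript start of NDE1). miR-320b had 5334 and 135 counts in the knockout libraries and did not pass (adjusted p = 0.119). The camera adjusted p was 5.88e-05 for mirtrons and 0.00312 for DROSHA-independent precursors. With an estimated correlation, the adjusted p was 0.587 for both. The camera result for mirtrons is also partly built in, as it rests on the same 8 miRNAs.

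Other miRNAs high in the knockout were miR-7706 (332.4-fold higher), miR-3615 (141.4-fold), miR-3605-3p (264.1-fold) and miR-7974 (17.5-fold). The largest fitted rises were of miRNAs with no parental count. They were at least 233.6-fold for miR-4286, 208.1-fold for miR-6832-5p, 179.6-fold for miR-4648, 176.9-fold for miR-7703, 169.0-fold for miR-6797-3p and 143.8-fold for miR-4709-5p. miR-4286 had 32 and 2 counts in the knockout libraries. Among fragments of other noncoding RNAs, which took 0.001664% ± 0.000589 of counts in the parental libraries and 0.517% ± 0.553 in the knockout (SD, n = 2 each), 3 of 4 tested rose, including miR-664a-3p, and 3 did so adjusted over the list alone, and the camera adjusted p was 0.0167 (adjusted p = 0.587 with an estimated correlation). Most of the knockout share was miR-1260b, with 761 and 0 counts in the 2 libraries, so that share is uncertain.

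The abundant canonical miRNAs fell by similar amounts. miR-222-3p was 15.2-fold lower, miR-191-5p 11.3-fold, miR-92a-3p 12.2-fold, miR-182-5p 13.3-fold, miR-100-5p 11.3-fold, let-7f-5p 15.9-fold and miR-10a-5p 12.3-fold. In the let-7 family, which restrains proliferation genes, 9 of 17 tested members fell, and in the miR-17 to miR-92a cluster with its paralogs 15 of 17 fell. In the epithelial miR-200 family 8 of 9 fell, with miR-141-3p 9.77-fold, miR-200b-3p 16.4-fold and miR-200c-3p 10.9-fold lower. All 11 tested members of the miR-10, miR-99, miR-100 and miR-125 list fell. Adjusted over the list alone, 9, 15, 8 and 11 fell, and no member of these 4 lists rose, against 236 of all 487 miRNAs lower. The camera adjusted p was 0.127, 0.0214, 0.0539 and 0.0539, and with an estimated correlation the adjusted p was 0.587 for each. With TMM factors the adjusted p of the miR-17 list was 0.1065. The largest fitted falls were of miRNAs without a knockout count, at least 14.9-fold for miR-374a-3p, 9.01-fold for miR-374b-5p, 6.96-fold for miR-17-3p, 6.85-fold for miR-27b-5p, 6.71-fold for miR-132-3p and 6.31-fold for miR-1301-3p. Over the 50 most abundant parental miRNAs outside the first 3 lists and the names unstable between replicates, the log2 change of mean CPM lay between -4.03 and -3.01 (SD 0.209, against 0.339 between the parental libraries), and with the 3 unstable names among the 50 between -5.02 and -3.01.

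These changes are of shares of miRNA counts. TMM factors left 0 calls by edgeR, with 238 miRNAs at an unadjusted p under 0.05, while DESeq2 size factors gave 114 higher and 150 lower, the DESeq2 Wald test 113 and 196, and scaling to the miR-320 family and miR-484 gave 8 and 388 and turned the sign of miR-320b, miR-320c, miR-320d, miR-1224-5p, miR-1234-3p and miR-7974. Without knockout library 2 there were 73 higher.

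**Figure D1:**
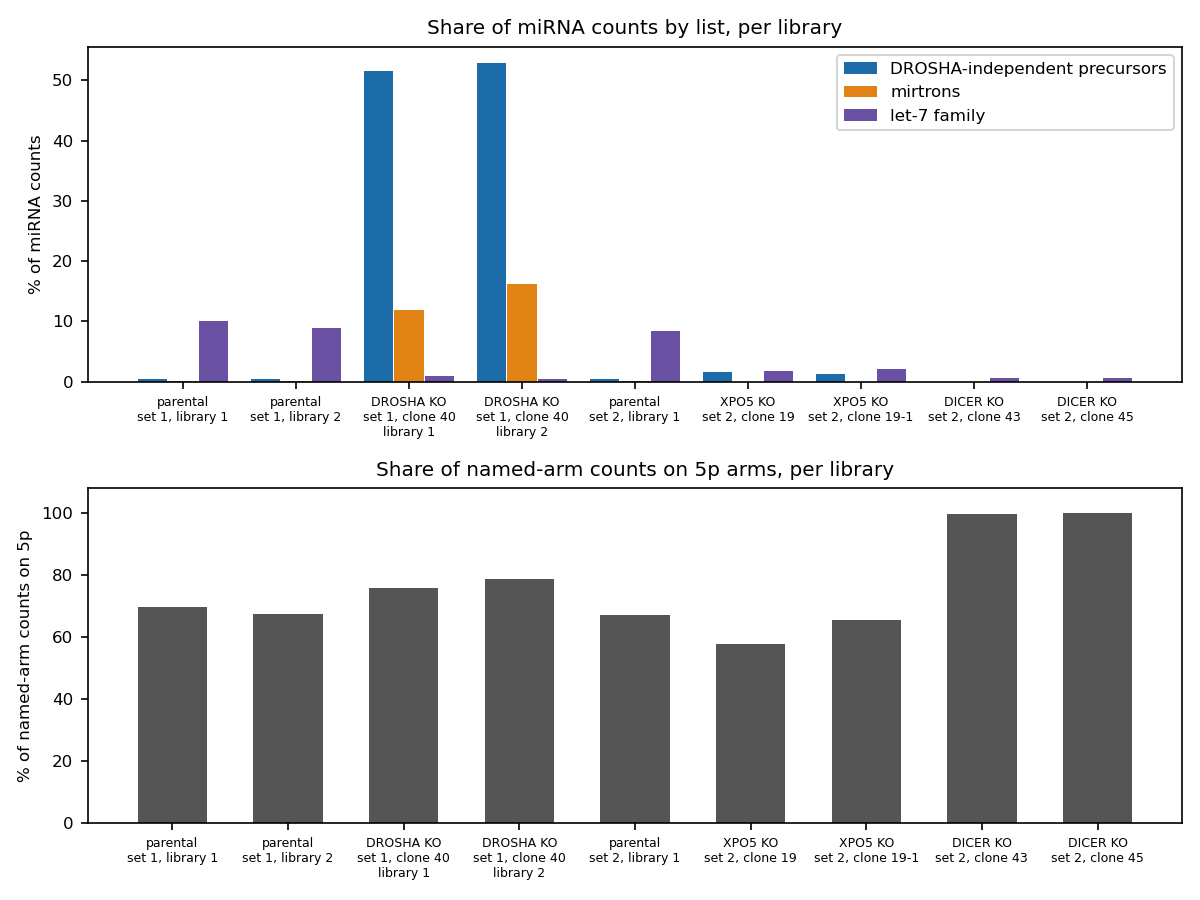
The upper panel shows the percentage of miRNA counts (y axis) in DROSHA-independent precursors, mirtrons and the let-7 family for each of the 9 libraries (x axis), and the lower panel the percentage of counts with a named arm that lie on 5p arms. DROSHA-independent precursors made up 51.57% and 52.9% of counts in the DROSHA knockout libraries, and 5p arms 99.71% and 99.88% of named-arm counts in the DICER knockout clones.

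Without XPO5, 6 of the 8 most abundant parental miRNAs did not pass the test, while members of the let-7 and miR-200 families fell. miR-200c-3p was 191-fold lower (log2 change -7.61, SE 1.20, adjusted p = 0.000265) and miR-141-3p 54.6-fold lower. miR-10b-5p was 8.41-fold higher (log2 change 3.07, SE 0.65, adjusted p = 0.00333), a call that was lost with copies summed and held with the parental libraries pooled. Of 409 miRNAs tested with edgeR, 21 were higher and 61 lower, and the median log2 change was -0.48.

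Among the most abundant parental miRNAs, miR-191-5p was 4.05-fold lower (adjusted p = 0.0207) and let-7f-5p 5.43-fold lower (adjusted p = 0.011). The log2 change was 0.27 (SE 0.33) for miR-21-5p, 0.19 (SE 0.57) for miR-222-3p, -0.41 (SE 0.61) for miR-92a-3p, -0.78 (SE 0.56) for miR-182-5p, -0.03 (SE 0.47) for miR-10a-5p and 1.02 (SE 0.60) for miR-22-3p, and none passed the test. miR-100-5p was 3.93-fold lower. With TMM factors the change of miR-92a-3p was 0.25 and that of miR-10a-5p 0.64. miR-31-5p (2.47-fold) and miR-27b-3p (3.62-fold), both high in the knockout, did not pass. In the let-7 family 7 of 16 tested members fell, and 9 did so adjusted over the list alone, with let-7a-5p 15.6-fold lower, while let-7i-5p (2.02-fold) and let-7g-5p (4.29-fold) did not pass. In the miR-200 family 6 of 9 fell, and 9 did so adjusted over the list alone. Its members miR-141-5p (133-fold), miR-200b-3p (7.74-fold) and miR-200c-5p (at least 10.6-fold) were lower. In the miR-17 to miR-92a cluster with its paralogs 5 of 16 fell, among them miR-18a-3p (71.2-fold) and miR-18a-5p (37.9-fold). The camera adjusted p was 0.0124 for let-7 and for miR-200 and 0.0335 for the cluster. With an estimated correlation, the adjusted p was 0.667 for each. Fragments of other noncoding RNAs took 0.01982% ± 0.0202 of counts (SD, n = 2), and 1 of 3 tested rose, or 2 adjusted over the list alone (camera adjusted p = 0.0437, and adjusted p = 0.667 with an estimated correlation; adjusted p = 0.0911 with TMM factors). The one called, miR-1260b, had 159.82 ± 190.81 CPM in the knockout and is uncertain.

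The mirtrons miR-877-5p (6.58-fold) and miR-1224-5p (10.3-fold) were lower. No DROSHA-independent miRNA passed the test. The log2 change was 1.25 (SE 0.88) for miR-320a, 0.30 (SE 1.20) for miR-320b, 0.19 (SE 1.16) for miR-320c and 1.97 (SE 0.94) for miR-484. The largest fitted rises were of miR-550a-3-3p (at least 57.6-fold), miR-151a-5p (401.7-fold), miR-378a-3p (192.8-fold), miR-1275, miR-4709-5p (at least 10.5-fold) and miR-4522 (at least 9.42-fold). miR-151a-5p had 83 counts in the parental library of set 2 but 16557 and 12620 in those of set 1, and miR-550a-3-3p had 0 against 63 and 47. Neither was called with the parental libraries pooled. miR-378a-3p had 24 and 15436 counts in the parental libraries of set 1 and 20 in that of set 2, and miR-1275 had 219 and 4 counts in the XPO5 clones and 1 in the parental library. All 4 are uncertain. The rise of miR-10b-5p was not called with copies such as miR-10a-5p summed, and is also treated as uncertain. However, miR-10a-5p, the larger in the parental library, went from 43608 to 42584 CPM, so summing dilutes the rise and does not show shared reads. With the parental libraries pooled, miR-10b-5p was still called. TMM factors gave 32 higher and 27 lower, DESeq2 size factors 36 and 25, scaling to the miR-320 family and miR-484 4 and 105, and the parental libraries of both sets pooled 41 and 122 of 517 tested. Without clone 19 there were 11 and 28 calls, without clone 19-1 30 lower, and with libraries thinned to the smallest total edgeR made 0 calls, with 81 at an unadjusted p under 0.05, while the DESeq2 Wald test at full depth gave 18 higher and 45 lower.

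Without DICER, miR-21-5p reached 720050 and 754928 CPM in the DICER clones, and nearly all counts that remained were on 5p arms. miR-21-5p was 6.16-fold higher than in the parental library (log2 change 2.62, SE 0.38, adjusted p = 6.56e-06). miR-222-3p was 211.3-fold lower and miR-92a-3p 262.2-fold lower. Of 409 miRNAs tested with edgeR, 19 were higher and 264 lower, with a median log2 change of -5.40, or -2.77 with miRNAs without a count in one group at their bound.

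miR-10a-5p (2.52-fold), miR-221-5p (7.88-fold) and miR-454-5p (19.5-fold) were also higher, and miR-100-5p (log2 change 0.41, SE 0.55), miR-183-5p (1.64, SE 0.77), miR-181a-5p (0.05, SE 0.64), miR-30d-5p (-1.29, SE 0.62) and miR-10b-5p (0.16, SE 0.56) did not pass. Other large fitted rises were of miR-1275, miR-6892-5p (at least 23.7-fold), miR-1248 (at least 14.6-fold), miR-1260b (67.6-fold) and miR-151a-5p (31.7-fold). Of these, miR-1275 and miR-1260b jumped between libraries of a group and are uncertain. miR-151a-5p is uncertain too, as it had 83 counts in the parental library of set 2 but 16557 and 12620 in those of set 1. With the parental libraries pooled, its log2 change was -1.72. miR-191-5p was 22.9-fold lower, miR-182-5p 8.03-fold, let-7f-5p 20.5-fold and miR-22-3p 152.8-fold. No count remained of miR-941 (at least 616.5-fold lower), miR-125b-1-3p (264-fold), miR-101-3p (134.6-fold), miR-500a-3p (109.3-fold), miR-339-3p (108.3-fold) or miR-320b (100.2-fold). The let-7 family fell in 14 of 16 members, the miR-17 to miR-92a cluster with its paralogs in 15 of 16 and the miR-200 family in 8 of 9, and adjusted over the list alone 15, 15 and 9 fell. Their camera adjusted p was 0.306, 0.0601 and 0.306, and 264 of all 409 miRNAs were lower. Fragments of other noncoding RNAs took 0.03379% ± 0.000495 of counts in the DICER clones (SD, n = 2) and 0.00158% in the parental library (exact 95% interval 0.00105 to 0.00228), and 2 of 3 tested rose, while adjusted over the list alone 2 rose and 1, miR-664a-3p, fell (camera adjusted p = 0.00414, and adjusted p = 0.855 with an estimated correlation; adjusted p = 0.06125 with TMM factors). The 4 tested DROSHA-independent miRNAs and the 2 tested mirtrons fell here. miR-320a was 161.4-fold lower, miR-484 87.4-fold, miR-877-5p 57.5-fold, miR-320c at least 2.03-fold and miR-1224-5p at least 7.85-fold. miR-451a, which AGO2 matures without DICER, had at most 7 counts in any library and was not tested.

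TMM factors gave 59 higher and 122 lower, DESeq2 size factors 61 and 117, totals without miR-21-5p 41 and 169, and the parental libraries of both sets pooled 32 and 332 of 517 tested. In the first 3 of these the log2 change of miR-30d-5p turned to 1.68, 1.78 and 0.46. DESeq2 size factors turned that of miR-182-5p to 0.04. Scaling to the miR-320 family and miR-484 gave 73 and 0 (129 at an unadjusted p under 0.05) and turned the sign of let-7f-5p, miR-191-5p, miR-182-5p, miR-22-3p, miR-30d-5p, miR-484 and miR-877-5p, but miR-320a and miR-484 had only 10 and 13 counts in the DICER clones.

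The arms of a hairpin separated in the DICER knockout. In the parental library of set 2, 66.91% of counts with a named arm lay on 5p arms (95% interval 66.84 to 66.98), against 99.79% ± 0.12 (SD, n = 2) in the DICER clones and 61.65% ± 5.51 in the XPO5 clones. The share was 68.55% ± 1.57 in the parental libraries of set 1 and 77.12% ± 2.02 in the DROSHA knockout, where miR-320a and miR-484 carry no arm name. Without the 3 most abundant miRNAs of each library it was 66.13% ± 3.22 and 55.97% ± 4.57, a fall instead of a rise. Of 163 3p arms tested in the DICER knockout, 137 fell and none had a log2 change above 0, and of 185 5p arms 94 fell and 14 rose. Camera compares a set with the other tested miRNAs. Its adjusted p was 5.36e-06 for 5p arms, which were higher than the others, and 3.11e-09 for 3p arms, which were lower. With an estimated correlation, the camera adjusted p was 0.855 for both. As most other miRNAs are of the opposite arm, these are largely the same contrast. Within 101 hairpins the 5p arm had the higher log2 change in 94, with a median difference of 5.02 log2 units (permutation p = 1e-05, the smallest the flips can give). The median difference was 5.44 over the 36 hairpins with counts on both arms in both groups and 2.503 with arms without a count at their bound, where 76 hairpins had the higher 5p change and 25 the lower. Read lengths are not in the files. The median difference was 0.19 in the XPO5 knockout (permutation p = 0.303) and -0.31 over 115 hairpins in the DROSHA knockout (permutation p = 0.289).

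**Figure D2:**
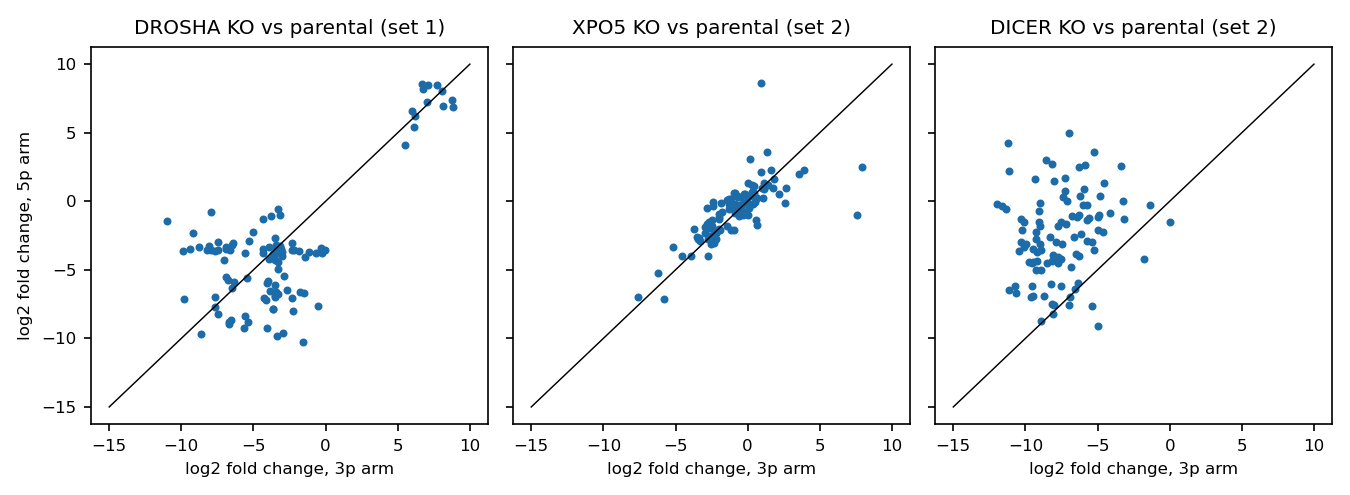
Each point is a hairpin with both arms tested, with the log2 fold change of its 3p arm (x axis) and its 5p arm (y axis) in each knockout against the parental libraries of its set, with fitted values for arms without a count, and the line marks equal change. In the DICER knockout 94 of 101 hairpins lie above the line, and the median difference of 5p minus 3p is 5.02. With arms without a count at their bound, 76 have the higher 5p change.

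Set against the XPO5 knockout, the DICER knockout had 24 miRNAs higher and 240 lower of 409 tested with edgeR, and the 24 higher were all 5p arms. Of 185 5p arms 86 fell, with a median log2 change of -1.92, or -1.37 at the bound. This comparison does not rest on the single parental library. miR-21-5p was 5.12-fold higher (log2 change 2.36, SE 0.28, adjusted p = 7.57e-07), and miR-222-3p was 240.5-fold lower. Within hairpins the median difference of 5p minus 3p was 4.80 (permutation p = 1e-05, the smallest the flips can give), or 2.05 with arms without a count at their bound, where 73 of 101 hairpins had the higher 5p change and 28 the lower.

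miR-10a-5p (2.58-fold), miR-100-5p (5.23-fold), miR-183-5p (17.6-fold), miR-221-5p (11.1-fold), miR-454-5p (28.0-fold), miR-18a-5p (15.6-fold), miR-450b-5p (14.3-fold), miR-135b-5p (14.4-fold) and miR-6892-5p (at least 23-fold) were higher. miR-31-5p was 16.2-fold lower, miR-22-3p 309.1-fold, miR-10b-5p 7.52-fold, miR-92a-3p 197.9-fold and miR-27b-3p 105.6-fold. No count remained of miR-941, miR-140-3p, miR-320b, miR-101-3p, miR-625-3p or miR-2277-5p. miR-320a (385-fold), miR-484 (341.5-fold), miR-320c (at least 2.36-fold) and miR-877-5p (8.74-fold) were lower, and miR-1224-5p, with 6 counts in the XPO5 clones, did not pass. miR-181a-5p (-1.12, SE 0.52) and miR-30d-5p (0.48, SE 0.53) did not pass either. TMM factors gave 59 higher and 128 lower, DESeq2 size factors 59 and 130, totals without miR-21-5p 51 and 144, and scaling to the miR-320 family and miR-484 180 and 0 (194 at an unadjusted p under 0.05). That last scaling turned miR-877-5p to 6.04, miR-31-5p to 5.97, miR-10b-5p to 6.47 and miR-181a-5p to 8.81, each past the threshold. The other named miRNAs that it turned did not pass. In the DICER clones miR-320a and miR-484 had only 10 and 13 counts.

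The effects of the knockouts differed from each other. The change without DROSHA exceeded that without XPO5 for 85 of 580 miRNAs and was below it for 78 (64 and 34 with TMM factors). miR-877-5p (log2 difference 9.95, SE 0.96, adjusted p = 0.000165) and miR-1224-5p (9.89, SE 0.97) had the smallest p. Against the DICER effect the DROSHA effect was higher for 157 miRNAs and lower for 33 (69 and 26 with TMM factors), with miR-320a first (14.42, SE 1.15, adjusted p = 1.25e-05). The log2 changes of the XPO5 and DICER knockouts correlated across miRNAs with r = 0.347, against 0.589 in 50 simulations of unchanged groups sharing the parental library. The covariance was 2.883, against 0.742. The knockouts shared 51 lower miRNAs, where independent lists would share 39.4, and 3 higher, where they would share 0.98. Both comparisons share 1 parental library, and miRNAs are not independent replicates.

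Thinned to 89812 counts, the parental libraries listed 401.5, 409.5 and 419.3 miRNAs, the XPO5 clones 393.4 and 358, the DICER clones 186.4 and 196.7, and the DROSHA knockout 571.2 and 506. The parental library of set 2 correlated with those of set 1 at r = 0.977 and 0.966 across 474 miRNAs, and these with each other at 0.975. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 52.95 or more. Markers of other cells were low. The stroma and endothelium markers made up 0.3028% of counts in the parental library of set 2 (95% interval 0.2948 to 0.311) and 0.07523% ± 0.00372 (SD, n = 2) in the XPO5 clones, where 4 of 7 fell, with miR-145-5p 6.46-fold and miR-143-3p 9.5-fold lower (camera adjusted p = 0.0335, and adjusted p = 0.667 with an estimated correlation). Of the neuron markers miR-9-5p (7.61-fold) and miR-9-3p (9.96-fold) fell there. The stroma and endothelium markers also fell to 0.00602% ± 0.000633 in the DICER clones, where 6 of 7 fell (camera adjusted p = 0.463), and went from 0.2555% ± 0.0129 in the parental libraries of set 1 to 0.02963% ± 0.0136 in the DROSHA knockout, where 4 of 7 fell (camera adjusted p = 0.322). Of the 3 neuron markers, 3 fell without DICER and 2 without DROSHA.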

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

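All weighing tests in this part were chosen after the results were seen. The effects of the knockouts differed in a direct test of the difference. Both DROSHA knockout libraries come from a single clone, so an effect of that clone cannot be told from loss of DROSHA. Against XPO5, the DROSHA effect was higher for 85 miRNAs and lower for 78, or 64 and 34 with TMM factors. Against DICER, it was higher for 157 and lower for 33, or 69 and 26 with TMM factors.

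Canonical miRNAs kept a small share of counts without DROSHA. The log2 change of the 50 most abundant, without the first 3 lists and names unstable between replicates, spanned -4.03 to -3.01, or -5.02 to -3.01 with the unstable names. The SD of that change, taken between means of 2 libraries, was 0.616 times the SD between the 2 single parental libraries. Averaging lowers the first SD, so the low ratio is partly built in. The remaining profile resembled the parental one, which carry-over of parental reads or parental cells would also give. Against some of these 50 being processed without DROSHA, 0 of the 50 lay over 4-fold above the median in both libraries. Less abundant miRNAs were not part of this test, so it does not speak for them. Outside the first 3 lists, 95 placed miRNAs were called higher, and 53 of them had a hairpin at an intron end or transcript start. A low uniform DROSHA activity stays open, untested. With carry-over, or for full loss of DROSHA if some activity remained, the falls of canonical miRNAs may be understated.

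5p arms were kept over 3p arms without DICER. As the whole cause, carry-over of parental reads would keep both arms alike, but the median difference within hairpins was 5.0161 log2 units, or 2.503 with arms without a count at their bound. A share effect of miR-21-5p would scale both arms alike, but the difference was 5.4441 over hairpins with counts on both arms in both groups. That loss of DICER keeps 5p arms of hairpins cut by DROSHA may be the cause and stays open, since the difference of 4.802 against the XPO5 clones, or 2.0471 with arms without a count at their bound, comes from the same DICER libraries. Whether these reads have the length of mature miRNAs stays open too, as read lengths are not in the files.

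The 21 miRNAs higher without XPO5 could partly be an effect of the single parental library. Of them, 7 had a parental library of set 1 within 4-fold of the knockout level or above it. With copies summed, 6 were no longer called. Of these, miR-1275, miR-486-3p and miR-625-5p had no other name to sum, so their loss does not bear on shared reads. Only miR-103a-1-3p, miR-10b-5p and miR-550a-3-3p lost the call when merged with other names. A call kept by a name with no other to sum, such as miR-2110 or miR-7706, does not bear on shared reads either. Summing copies therefore does not decide this cause for the 21. Against pooled parental libraries, 15 were still higher. For these 21 miRNAs, reads missing from the parental library and loss of XPO5 cannot be told apart, since neither count reached the share set for a decision. miR-151a-5p, miR-378a-3p, miR-103a-1-3p, miR-550a-3-3p, miR-625-5p and miR-1275 were lost with pooled parental libraries.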

How the results depend on the processing

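Totals without miR-21-5p, summing of copies, leaving out unstable miRNAs and 5 restrictions of the arm comparison were chosen after seeing the data. Among single miRNAs, lists and shares, 1683 alternative values kept direction and side of the threshold, 178 fell below it, 41 passed it, 21 moved and 55 turned sign. The cause was not tested where none is given. With TMM factors, 152 values of single miRNAs and lists stayed the same, 51 fell below the threshold, 7 passed it and 8 turned sign. For single miRNAs alone these counts were 102, 11, 7 and 6 with DESeq2 size factors and 55, 40, 1 and 30 with scaling to the miR-320 family and miR-484. With TMM factors the DROSHA knockout had 0 higher and 0 lower by edgeR (238 miRNAs at an unadjusted p under 0.05), the XPO5 knockout 32 and 27, the DICER knockout 59 and 122, and DICER against XPO5 59 and 128. The median log2 change then moved by 1.24, 0.64, 1.99 and 1.25. For the difference of effects TMM gave 34 lower for DROSHA against XPO5 and 69 higher for DROSHA against DICER. DESeq2 size factors in edgeR gave 150 lower in the DROSHA knockout, 36 and 25 in the XPO5 knockout, 61 and 117 in the DICER knockout and 59 and 130 in DICER against XPO5. Scaling to the miR-320 family and miR-484 gave 8 and 388 for DROSHA (median shift -5.89), 4 and 105 for XPO5 (-1.53), 73 and 0 for DICER (6.40; 129 at an unadjusted p under 0.05) and 180 and 0 for DICER against XPO5 (7.65; 194 at an unadjusted p under 0.05). The DESeq2 Wald test, run with library totals and neither of these scalings, gave 113 and 196 for DROSHA, 18 and 45 for XPO5, 17 and 198 for DICER and 22 and 195 for DICER against XPO5. The miR-320 and miR-484 reference is itself what rose without DROSHA and had few counts without DICER.

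With at least 200 counts, fewer miRNAs were tested, with 26 higher for DROSHA, 8 higher for XPO5, 11 and 166 for DICER and 15 and 157 for DICER against XPO5. No filter gave 329 higher for DROSHA. Thinned libraries, with fewer counts, gave 137 lower for DROSHA, 0 and 0 by edgeR for XPO5 (81 at an unadjusted p under 0.05) and 9 and 175 for DICER. Pooled parental libraries gave 41 and 122 for XPO5 and 32 higher for DICER. Totals without miR-21-5p gave 41 and 169 for DICER and 51 and 144 for DICER against XPO5. Leaving out miRNAs unstable between replicates gave 23 and 88 for XPO5. The replicate block gave 113 higher and 185 lower for DROSHA, but deviations of libraries with the same number correlated at -0.0033, so the numbers do not pair them. With at least 3 counts, 247.6 miRNAs were detected in parental libraries of set 1, 325.0 in DROSHA, 261.9 in parental set 2, 228.2 in XPO5 and 108.2 in DICER libraries. With only hairpins with both arms tested, the camera p of 5p arms in the DROSHA knockout was 0.848 against 0.0294, that of 3p arms 0.848 with the direction turned, and that of 5p arms in the XPO5 knockout 0.575 with the direction turned. The median 5p minus 3p difference in the DICER knockout stayed positive in the 6 alternatives, from 2.503 to 5.44 with p = 1e-05 by permutation in each, the smallest the flips can give.

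Leaving out each library in turn, with a lone library assumed to vary like the others, gave 73 to 111 higher and 188 to 209 lower for DROSHA, 11 to 27 and 28 to 76 for XPO5, 13 to 19 and 222 to 232 for DICER, and 18 to 23 and 182 to 200 for DICER against XPO5. The 73 came without DROSHA knockout library 2, the 11 and 28 without XPO5 clone 19, and without clone 19-1 there were 30 lower. Log2 changes ranged from -0.23 to 0.47 for miR-10b-5p and -0.45 to 0.43 for miR-181a-5p in DICER, and from -0.43 to 0.62 for miR-222-3p, -3.003 to 1.22 for miR-320b and -0.23 to 0.56 for miR-320c in XPO5. The parental library of set 2 could not be left out, as its comparisons have no other. The planned pseudocounts for normalized values did not apply to counts, and a crossed block was not run, as its condition was not met.

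Log2 changes that turned sign follow. DESeq2 size factors gave 1.04 for miR-181a-5p in DICER against XPO5, 0.0427 for miR-182-5p and 1.78 for miR-30d-5p in DICER, and 0.78 for miR-10a-5p, 0.0685 for miR-182-5p and 0.38 for miR-92a-3p in XPO5. TMM gave 1.08 for miR-181a-5p in DICER against XPO5, 1.68 for miR-30d-5p in DICER, and 0.64 for miR-10a-5p and 0.25 for miR-92a-3p in XPO5. It turned the camera direction of the miR-183 cluster (adjusted p = 0.935) and miR-26 family (adjusted p = 0.947) in XPO5 and of the miR-221 and miR-222 list (adjusted p = 0.94) and miR-30 family (adjusted p = 0.608) in DICER. Pooled parental libraries gave -1.72 for miR-151a-5p and -0.30 for miR-181a-5p in DICER and -0.45 for miR-378a-3p in XPO5. Totals without miR-21-5p gave 0.62 for miR-181a-5p in DICER against XPO5, 0.46 for miR-30d-5p in DICER and 0.0063 for miR-10a-5p in XPO5. Scaling to the miR-320 family and miR-484 gave, in DICER against XPO5, 6.47 for miR-10b-5p, 8.81 for miR-181a-5p, 1.22 for miR-22-3p, 1.19 for miR-222-3p, 2.35 for miR-27b-3p, 5.97 for miR-31-5p, 0.0172 for miR-320a, 0.0786 for miR-484, 6.04 for miR-877-5p and 1.36 for miR-92a-3p. In DICER it gave 3.90 for let-7f-5p, 5.35 for miR-182-5p, 3.90 for miR-191-5p, 0.68 for miR-22-3p, 6.92 for miR-30d-5p, 0.53 for miR-484 and 1.88 for miR-877-5p. In DROSHA it gave -0.27 for miR-1224-5p, -0.52 for miR-1234-3p, -1.08 for miR-320b, -1.54 for miR-320c, -0.79 for miR-320d and -2.76 for miR-7974. In XPO5 it gave -1.24 for miR-21-5p, -0.54 for miR-22-3p, -1.27 for miR-222-3p, -0.15 for miR-31-5p, -0.25 for miR-320a, -1.34 for miR-320b and -1.31 for miR-320c. The DROSHA knockout libraries, with the fewest counts, limit what can be seen of low miRNAs.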

Other observations

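In the DROSHA knockout, 8 of 9 tested members of the miR-30 family, 6 of 6 of the miR-181 family, 6 of 9 of the miR-15 and miR-16 family, 3 of 5 of the miR-183 cluster and 4 of 4 of the miR-148 and miR-152 list fell by edgeR, against 236 of all 487. The camera adjusted p of these lists was 0.0709, 0.101, 0.178, 0.366 and 0.186. The arms of the miR-29a hairpin moved apart without DICER, with miR-29a-5p 6.61-fold higher and miR-29a-3p 286.1-fold lower. miR-34c-5p was 6.80-fold higher. The HOX-cluster miRNA miR-196b-5p was at 1158 CPM in the parental library of set 2, 5523 CPM without XPO5 (adjusted p = 0.0798, edgeR) and 973 CPM without DICER. In the imprinted 14q32 cluster, miR-654-3p (6.86-fold) and miR-381-3p (8.18-fold) fell without XPO5. miR-196b-3p was 15.4-fold higher there. The blood marker miR-486-5p had 926 and 33 counts in the XPO5 clones and 216 in the parental library, and did not pass. miR-486-3p passed (adjusted p = 0.0277, edgeR) with 49 and 0 counts in these clones and 0 in the parental library, so its rise rests on 1 clone and is uncertain. The liver, muscle and C19MC lists had 0 members with enough counts to test in any comparison. Of the other lists of canonical families, the miR-221 and miR-222, miR-23 to miR-27, miR-26, miR-29, miR-34 and miR-181 lists had 0 members past the edgeR threshold without XPO5.

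One hypothesis was written before its test. miRNAs that rise without DROSHA may come from hairpins at intron ends or transcript starts, where splicing or transcription makes an end. Of 110 miRNAs called higher and placed on the genome, 62 had such a hairpin, against 8 of 376 others (odds ratio 59.4, Fisher's exact test, two-sided p = 7.29e-39). A first gene match placed only 53.2% of names and gave an odds ratio of 105, and the match was widened after that was seen. Intron ends, within 5 nt, accounted for 58 against 0, and transcript starts, within 30 nt, for 5 against 8 (Fisher's exact test, two-sided p = 0.182). Outside the special lists the odds ratio was 57.7, and per hairpin 56.1. Only miRNAs with at least 20 counts summed over set 1 were tested. Those with few parental counts, such as miR-1228-3p with 1 against 26 in the knockout, could enter only through knockout counts. The 0 among the others and the odds ratios are therefore partly built in. Within that limit the values go with the hypothesis for intron ends, while for transcript starts alone the Fisher p missed the threshold.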
